A study of Homo sapiens with 6 samples.

How the data were processed

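Gene expression was compared on 2-colour cDNA microarrays between HCT116-CloneK, an X-ray-sensitive clone of the colorectal cancer line HCT116, collected 24 hr after a dose of 4 Gy, and unirradiated HCT116-Clone10, a clone whose response to X-rays resembles that of parental HCT116, per the labels. The array set has 2 parts that carry different cDNA clones, and each part was hybridized on 3 arrays, 6 in all. Replicates 1 and 3 of each part had CloneK in Cy5 and Clone10 in Cy3, and replicate 2 had the dyes exchanged. Per the labels, the CloneK RNA came from several batches that were pooled, so the 3 arrays of a part may share 1 RNA pool, and the tests below measure the spread between arrays. Irradiation and cell clone differ together on every array, so the design gives no separate effect of either.

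The deposited values are log2 ratios of the 2 channels for each spot. Per the labels, the authors scanned the slides on a ScanArray Express, quantified the images in QuantArray 3.0, and transformed the data with the spreadsheet macro Normaliser2, which subtracted a background for each sub-array and normalized each sub-array by regression. Per the labels, spots were removed when their signal was under 2.5 times the sub-array background, under 5% of spot intensity, or damaged or streaked. The deposited log2 ratios were used without further normalization. The labels do not say which channel is the numerator. For replicates 1 and 3, CloneK was both channel 2 and the Cy5 channel, so a positive value is read as higher in CloneK under either usual convention, which makes that reading likely. The sign of replicate 2 depends on the convention. By a rule fixed before the data were examined, replicate 2 was turned only where it correlated negatively with both other arrays of its part. This turned it in part A and left it as deposited in part B, where the rule did not settle the sign. In part A the correlations of replicate 2 with replicates 1 and 3 were only −0.022 and −0.033, so its sign is open there as well. In part B they were −0.101 and 0.033. The average covariance of replicate 2 with the other arrays was below 0 in part B as in part A. If both parts were processed alike, a single convention would give replicate 2 the same sign in both, as the dyes were exchanged alike. The reading used then follows no single convention, and the list tests join both parts under it. Means over 3 arrays therefore rest on this reading, and values of replicate 2 are given as deposited.

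Each table holds 19200 spots, a pair of neighbouring spots for each of 9600 clones. The 2 spots of a clone were averaged on each array, and clones with a value on all 3 arrays were tested: 9468 in part A and 9343 in part B, 18811 together. Gene names came from the platform annotation, updated through gene numbers against a reference table of GRCh38.p14, which changed 0 symbols. In part A, 7872 spots had 1 gene symbol, 346 had several and 10982 had none. In part B, 8000 spots had 1 symbol, 312 had several and 10888 had none. Only clones with 1 symbol were named, which gave 7781 tested clones of 6174 genes. The number of arrays limits the precision of every value.

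The mean log2 ratio of each clone was tested against 0 with limma's moderated test (lmFit and eBayes, limma 3.58.1 in R 4.3.3), 1 fit for each part, with Benjamini-Hochberg adjustment over both parts and a threshold of 0.05. Standard errors are those of limma. A count of clones changed 2-fold on all 3 arrays was made without a test. The 20 gene lists were tested with camera at a preset correlation of 0.01 on a matrix with 1 value per gene and array, and beside it with an estimated correlation and with fry. Genes to be named were fixed by rule: the 10 highest and 10 lowest called genes with the same sign on all 3 arrays, filled up with the smallest unadjusted p where too few were called, up to 3 members of each list with the largest moderated statistic, and 19 genes of the p53 response, cell cycle and DNA repair, of which CDKN1A and ATM were among the named clones tested. The lists, the rule and other settings to be tried were set before the data were examined. The other settings covered centring, scaling and quantile normalization of arrays, missing values, single spots, duplicate spots with an estimated correlation, the mean of a gene's clones, a dye term, array weights, variance priors, an unmoderated statistic, adjustment within parts, thresholds, the sign of replicate 2, and leaving out each replicate. Subtraction of the median of neighbouring spots (2 lines of 24 spots and 4 spots on each side) and uniform signs of replicate 2 were chosen after seeing the data.

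The clone test was tested on simulated data with the observed spread between arrays: of 200 changed clones among 18811, it called 0% at a log2 change of 0.5, 0% at 1, 60.5% at 2 and 86.5% at 3. Correlations between different clones of a gene, between clones with the same annotated sequence and between neighbouring genes were compared with 1000 permutations of the pairs. Intervals of covariances are 95% bootstrap intervals from 1000 draws over clones. These steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. No spot intensities were used here.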

Results

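The data are log2 expression ratios between X-ray-sensitive HCT116-CloneK cells, 24 hr after 4 Gy, and unirradiated HCT116-Clone10 cells, on 3 arrays for each of 2 parts of a cDNA clone set. In part A, 18920, 18851 and 18746 spots of replicates 1, 2 and 3 had a value, and the SDs of the log2 ratios were 0.40, 0.40 and 0.65. In part B, 18724, 18792 and 18484 spots had a value, and the SDs were 0.50, 0.44 and 0.57. Median log2 ratios lay between −0.01 and 0.04. The comparison addresses which genes differ between a radiosensitive clone after irradiation and an untreated clone of ordinary sensitivity. A positive value is read as higher in CloneK.

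No clone passed the threshold, so the 10 named genes of each side were chosen by smallest unadjusted limma p, not by size of mean. They also had the same sign on all 3 arrays under the sign reading used. DOK1, which encodes a docking protein of tyrosine kinase signalling, and SYS1, which encodes a Golgi trafficking protein, had the largest positive means of these. Deposited log2 ratios of DOK1 were 1.17, 1.52 and 1.89 on replicates 1, 2 and 3, with a mean of 1.52 ± 0.19 (SE, n = 3; limma adjusted p = 0.807). Those of SYS1 were 1.37, 1.09 and 2.89, with a mean of 1.79 ± 0.35 (SE, n = 3; limma adjusted p = 0.807). With replicate 2 turned in part B as well, the mean of DOK1 was 0.51 and that of SYS1 1.06, beside 1.05 for DLGAP1-AS1 and 0.97 for TBC1D23. Under the reading used PDXDC1 had the most negative mean of the genes so chosen, at −1.13 ± 0.17 (SE, n = 3; limma adjusted p = 0.807). ORC3, a subunit of the origin recognition complex that licenses DNA replication, had a mean of −1.06 ± 0.16, and USP39, a splicing factor, had a mean of −1.06 ± 0.15 (SE, n = 3 each). With replicate 2 as deposited in both parts the mean of PDXDC1 was −0.52 and that of ORC3 −0.19, while USP39 stayed at −1.06. With it turned in both parts USP39 was at −0.27. REV3L, the catalytic subunit of the translesion DNA polymerase zeta, had a mean of −0.95 ± 0.18, and KIAA0586, a centrosomal protein gene, had a mean of −0.98 ± 0.16 (SE, n = 3 each). They were at −0.46 and −0.38 with replicate 2 as deposited. None of these genes passed the threshold.

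The other 8 genes of the positive side were KANSL1-AS1, DLGAP1-AS1, ZBTB33, RPS19, TBC1D23, PTPDC1, EPC2 and KPNA4, with mean log2 ratios from 0.65 (RPS19) to 1.05 (DLGAP1-AS1). With replicate 2 as deposited the 7 of them in part A had means from 0.095 (KPNA4) to 0.46 (EPC2), with DLGAP1-AS1 at 0.27, and with it turned KANSL1-AS1 was at 0.26. On the negative side, RHOT1, EGFL6, KALRN, WDR59 and KCNJ10 had means from −0.89 (WDR59) to −0.75 (RHOT1). As deposited, RHOT1, WDR59 and KCNJ10 had means of −0.20, −0.44 and −0.33, and with replicate 2 turned EGFL6 and KALRN had means of −0.24 and −0.40. Of the 20 genes, 14 lie in part A, where replicate 2 was turned, and their deposited ratio on replicate 2 had the sign opposite to that on replicates 1 and 3. The choice of genes with the same sign on all 3 arrays under the reading used fixes this, so it says nothing about that reading. ORC3, for example, was deposited at −0.95 on replicate 1, 1.31 on replicate 2 and −0.92 on replicate 3. The 6 genes in part B, DOK1, SYS1, KANSL1-AS1, USP39, EGFL6 and KALRN, had the same sign on all 3 arrays as deposited, which the choice also fixes. EGFL6 was deposited at −0.66, −0.82 and −0.88, and USP39 at −0.92, −1.18 and −1.07, on replicates 1, 2 and 3.

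**Figure D1:**
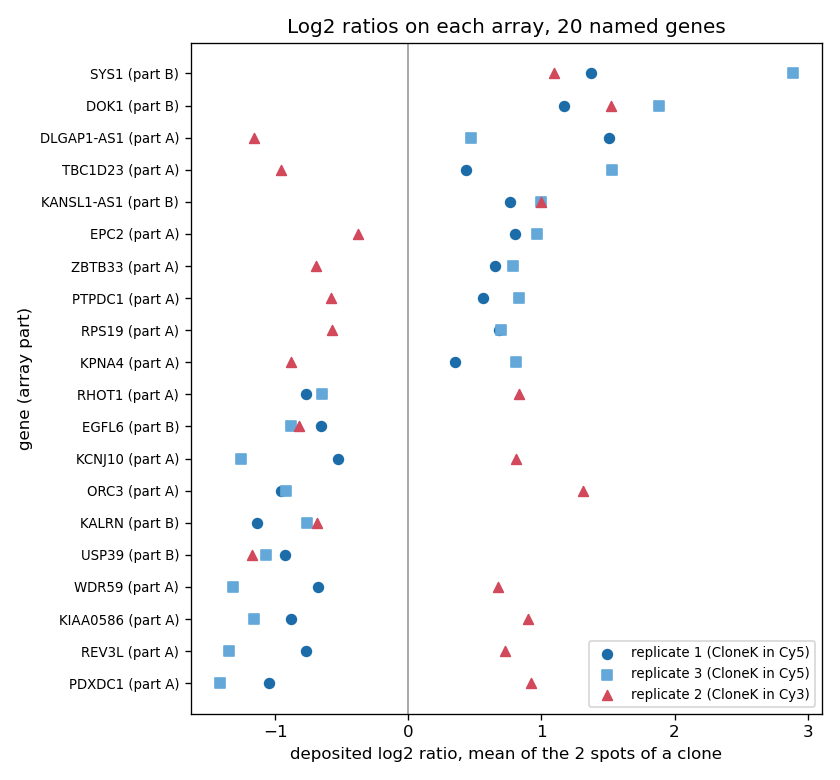
Deposited log2 ratios (horizontal axis) of named genes (vertical axis, with the array part), 1 point per array. The 10 genes with positive and 10 with negative means were chosen by smallest unadjusted limma p, not by size of mean. Circles and squares are replicates 1 and 3 with CloneK in Cy5, and triangles are replicate 2 with CloneK in Cy3. The choice asked for the same sign on all 3 arrays under the sign reading used. It thereby fixes that the triangle lies across 0 from the other points in the 14 genes of part A. It also fixes that the triangle lies on the same side in the 6 genes of part B.

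Across all clones, 0 of 18811 passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.807. At an unadjusted p under 0.05 there were 1106 clones, 365 with positive and 741 with negative means, which is 5.88% of clones. In simulated data with the observed spread, 5.59% to 5.98% of unchanged clones had such a p. Part A gave 646 of these clones with replicate 2 turned and 494 with it as deposited, and part B gave 460 with it as deposited and 600 with it turned. The total was 954 with replicate 2 as deposited in both parts and 1246 (6.62%) with it turned in both. DOK1, SYS1 and 1 clone without a gene name were at least 2-fold from 0 on all 3 arrays, the unnamed clone in the negative direction. With replicate 2 as deposited in both parts 6 clones were at least 2-fold on all 3 arrays, and with it turned in both parts 1 was. The test called no clones in simulated data with 200 clones at a log2 change of 1. Differences of that size were thus not detectable with 3 arrays at that number of changed clones, and other numbers were not simulated.

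CDKN1A, the cell cycle inhibitor p21 that p53 induces after DNA damage, was measured by 1 clone in each part, and the clones differed in sign. In part A, CDKN1A was deposited at −0.23, 0.31 and −1.30, with a mean of −0.61 ± 0.24 (SE, n = 3; limma adjusted p = 0.825). In part B, CDKN1A was deposited at 0.20, 0.24 and 0.26, with a mean of 0.23 ± 0.15 (SE, n = 3; limma adjusted p = 0.825). ATM, the kinase that signals DNA double-strand breaks, had a mean of −0.29 ± 0.17 (SE, n = 3; limma adjusted p = 0.825). Of the 17 p53 targets measured, 6 had positive and 11 had negative means, with a median of −0.02 (camera adjusted p = 0.915). Negative means numbered 9 with replicate 2 as deposited in both parts and 10 with it turned in both. With it turned in part B alone, 9 means were positive and 8 negative, with a median of 0.025. TGFA and SESN1 had means of 0.26 ± 0.15 and 0.34 ± 0.20 (SE, n = 3 each), which were 0.12 and 0.07 with replicate 2 turned. The smallest unadjusted p of the list belonged to CDKN1A in part A under the reading used, to CYFIP2 (mean −0.47) as deposited and to DUSP1 (mean −0.63) with replicate 2 turned in both parts. The other p53 response genes chosen in advance were not analysed here.

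List counts from here on hold for the reading used, each with its range over all 4 sign settings of replicate 2 (each part turned or not). Among the cell cycle lists, 11 of 18 DNA replication and G1/S genes (range 10 to 11) and 7 of 14 mitosis and G2/M genes (6 to 7) had negative means (camera adjusted p = 0.587 for both). FOXM1, a transcription factor that drives G2/M genes, had the largest statistic of the mitosis list under the reading used and was deposited at −0.75, −0.82 and −0.53, with a mean of −0.70 ± 0.16 (SE, n = 3; limma adjusted p = 0.807). With replicate 2 turned in both parts the mean of FOXM1 was −0.16 and SMC2 (−0.43) led the list, and with it turned in part B alone MAD2L1 (−0.61) did. Under the reading used, SMC2 and NUSAP1 had means of −0.43 ± 0.18 and −0.39 ± 0.18 (SE, n = 3 each). In the replication list, ASF1B had a mean of −0.39, which was −0.10 with replicate 2 turned, and RFC5 a mean of 0.37, which was 0.080 without replicate 3. Adjusted over the list alone, ORC3 was the 1 replication clone past the threshold (limma adjusted p = 0.0073), against 0 over all clones. With replicate 2 as deposited in both parts no replication clone passed adjusted over the list alone (lowest limma adjusted p = 0.457). Of the 23 genes for DNA double-strand break repair and damage signalling, 12 had positive (range 11 to 13) and 11 had negative means (camera adjusted p = 0.855). Under the reading used their largest statistics were those of RAD1 (part A clone, mean −0.92 ± 0.21), BLM (0.40 ± 0.15) and RAD21 (0.55 ± 0.22), given as SE with n = 3 each. RAD21 was deposited at 0.28, −1.14 and 0.22, so its mean turned to −0.22 with replicate 2 as deposited. Under that sign TP53BP1 (part A clone, mean −0.70) led the list, and BLM was at 0.22.

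Proteasome subunits had negative means in 9 of 10 genes (range 7 to 9), with PSMD11 at −0.53 ± 0.17 and PSMA7 at −0.40 ± 0.18 (SE, n = 3 each). The count was 8 of 10 with replicate 2 as deposited in both parts, where PSMD11 was at −0.17, and 8 of 10 with it turned in both, where PSMA7 was at −0.13 and PSMD5 turned from −0.19 to 0.30. Their unadjusted camera p of 0.0488 was the smallest of the 20 lists under the reading used and became 0.587 after adjustment. It was 0.146 with replicate 2 as deposited in both parts and 0.204 with it turned in both. Oxidative phosphorylation subunits had positive means in 8 of 9 genes (range 7 to 8), among them ATP5F1C at 0.26 and SDHC at 0.22, while NDUFV1 was at −0.18 (camera adjusted p = 0.587). Of the 5 cytosolic ribosomal protein genes, 2 had positive means (range 2 to 3). RPS19 had a mean of 0.65 ± 0.15 (SE, n = 3). The RPS3 clones had means of −0.48 and −0.17, which were −0.16 and 0.65 with replicate 2 turned, and the RPL41 clones had means of 0.18, −0.42 and −0.0051. RPS19 was the 1 ribosomal clone past the threshold adjusted over the list alone (limma adjusted p = 0.0296). Its mean was 0.27 with replicate 2 as deposited, and no ribosomal clone passed (lowest limma adjusted p = 0.173). Tested for change in either direction with fry, the ribosomal list had an adjusted p of 0.00141, which became 0.624 with replicate 2 as deposited in both parts, 0.000811 with it turned in both and 0.588 with it turned in part B alone. Camera gave the list an adjusted p of 0.928, and 0.947 with an estimated correlation. The RPL41 clone at −0.42 turned to 0.21 with replicate 2 turned in both parts.

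The stress and signalling lists went both ways. Heat shock and unfolded protein response genes had negative means in 12 of 17 (range 8 to 12; camera adjusted p = 0.855), with ATF6 at −0.63 ± 0.20 and ERO1A at 0.87 ± 0.45 (SE, n = 3 each). ERO1A was deposited at 0.92, −0.43 and 2.12, and its mean was 1.52 without replicate 2 and 0.25 without replicate 3. Interferon-stimulated genes had negative means in 7 of 12 (range 7 to 10; camera adjusted p = 0.587), with RSAD2 at −0.41, IFIT5 at −0.45 and ISG20 at −0.28. RSAD2 was deposited at −0.59, 0.38 and −0.26, so the size of its mean rests on the turned replicate 2. IFIT5 was at −0.29 without replicate 1 and ISG20 at −0.12 without replicate 3. Of 17 immediate early and MAPK feedback genes, 10 had positive means (range 7 to 10; camera adjusted p = 0.932). FOSB was measured by 3 clones whose means were −0.76, 0.01 and 0.26, the last of which became −0.28 with replicate 2 turned. Apoptosis machinery genes had positive means in 9 of 15 (range 8 to 10; camera adjusted p = 0.712), with DAPK1, a death-associated kinase, at 1.19 ± 0.45 and BCL2L2 at −0.54 ± 0.21 (SE, n = 3 each). DAPK1 was deposited at 1.27, −0.13 and 2.42, and its mean was 1.84 without replicate 2 and 0.57 without replicate 3. The mean of BCL2L2 was −0.27 without replicate 3. Antioxidant and glutathione enzymes had positive means in 7 of 12 (range 6 to 7; camera adjusted p = 0.855), with PRDX4 at 0.69 for 1 clone and −0.08 for another. Of 4 NF-kappaB and inflammatory response genes 3 had negative means (range 2 to 3; camera adjusted p = 0.928). IRF1 was at −0.36, −0.66 without replicate 2 and −0.13 without replicate 3, and CD83 was at 0.26, or 0.053 with replicate 2 turned.

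Among the remaining lists, histones had negative means in 4 of 6 genes (range 4 to 5; camera adjusted p = 0.587). Both H2AJ clones were negative on all 3 arrays as deposited, with means of −0.41 and −0.32, or −0.21 and −0.082 with replicate 2 turned. Cholesterol and fatty acid synthesis genes had positive means in 7 of 12 (range 5 to 7; camera adjusted p = 0.712), with FADS2 at 0.30. ACACA was at 0.41 and turned to −0.04 with replicate 2 as deposited. Hypoxia and glycolysis genes had negative means in 5 of 8 (range 3 to 6; camera adjusted p = 0.915), with EGLN3 at −0.32 and EGLN1 at −0.21. Of 5 colon epithelial differentiation and Wnt target genes 3 had positive means (range 2 to 3; camera adjusted p = 0.932), and CEACAM6, a cell adhesion molecule of colon epithelium, was at −0.62 ± 0.18 (SE, n = 3), or −0.36 with replicate 2 turned. Mesenchymal and extracellular matrix genes had positive means in 4 of 9 (range 4 to 6, camera adjusted p = 0.855). The 6 ZEB2 clones had means from 0.02 to 0.34, or from −0.016 to 0.55 with replicate 2 turned. Among markers of other cell types, fibroblast markers had positive means in 3 of 6 genes (camera adjusted p = 0.928) and leukocyte markers in 2 of 3 (camera adjusted p = 0.855) under all 4 sign settings of replicate 2. With replicate 2 turned in both parts, fry's directional test gave the leukocyte markers an adjusted p of 0.0162, against 0.545 under the reading used. With an estimated correlation between genes, camera called 0 of the 20 lists, as with the preset one, and the smallest adjusted p was 0.942.

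Agreement between arrays set the limits of every gene value. Log2 ratios of the same clone on replicates 1 and 3 correlated with r = 0.195 in part A and r = 0.165 in part B, across clones, which are not independent replicates. Replicate 2, as deposited, gave r = −0.022 with replicate 1 and r = −0.033 with replicate 3 in part A. In part B it gave r = −0.101 with replicate 1 and r = 0.033 with replicate 3. On a single array the 2 spots of a clone correlated with r from 0.336 to 0.535, and adjacent spots of different clones with r from 0.158 to 0.256. Different clones of the same gene did not share their ratios: over 1978 pairs, replicate 1 of one clone and replicate 3 of the other gave r = −0.0002 (permutation p = 0.991). Across these pairs a second clone of a gene did not share the ratio of the first, although both clones of single genes such as H2AJ had the same sign.

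**Figure D2:**
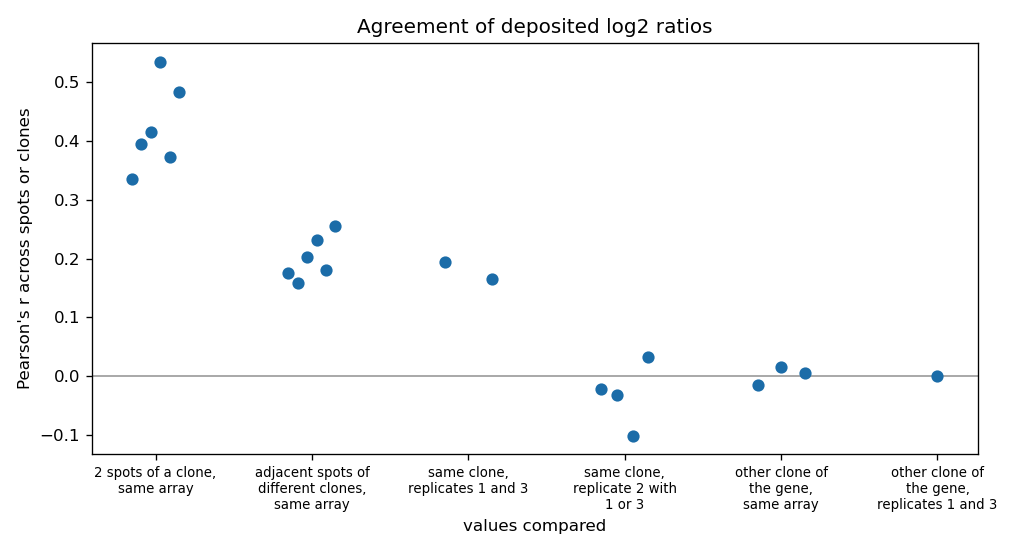
Pearson's r (vertical axis) of deposited log2 ratios for 6 kinds of pairs (horizontal axis), 1 point per array, pair of arrays or set of clone pairs. Spots of a clone correlate on each array (0.336 to 0.535) and clones correlate between replicates 1 and 3 (0.195 and 0.165), while different clones of a gene lie near 0.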

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

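CDKN1A stood out because its clones in the 2 parts lay on opposite sides of 0 on every array under the sign reading used: the mean log2 ratio was −0.61 in part A and 0.23 in part B, and the difference was not tested. As deposited, replicate 2 was at 0.31 in part A and 0.24 in part B, so under either uniform sign both clones lay on the same side of 0 on that array. The part B mean was 0.073 with replicate 2 turned, and the part A mean was −0.41 with it as deposited and −0.27 without replicate 3. Of 28 genes with 1 clone in each part and the same sign on all arrays within each part, 11 had the same direction in both parts and 17 had opposite directions (exact binomial p = 0.345, two-sided). The reading used turns replicate 2 in part A alone, which ties this count to replicate 2. A gene deposited with the same sign of replicate 2 in both parts could pass only with opposite directions. The count therefore does not show whether the parts agree.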

How the results depend on the processing

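The neighbourhood correction and the uniform signs of replicate 2 were chosen after seeing the data. No paired analysis was possible because each array already compares both cell clones and the 2 parts, which share replicate numbers, carry different clones. The count of clones past the threshold was 0 under 22 of 23 alternatives. It was 1106 (365 higher) at an unadjusted p of 0.05. The count of lists called was 0 under all 17 alternatives, of which fry's directional test was run under the reading used. Under the other signs of replicate 2, fry called leukocyte markers with it turned in both parts (adjusted p = 0.0162). For change in either direction, fry called ribosomal proteins under the reading used (0.00141) and turned in both parts (0.000811). The 3 clones at least 2-fold on all 3 arrays became 5 after quantile normalization, 11 with single spots, 1 with the mean of a gene's clones, 55 at 1.5-fold, 6 with replicate 2 as deposited in both parts, 1 with it turned in both, 1 after neighbourhood correction, and 11 to 38 when a replicate was left out. Fewer arrays or a lower threshold ask less of a clone, and the cause was not tested for the others. The correlation of replicates 1 and 3 became 0.134 (part A) and 0.125 (part B) with single spots, 0.162 in part A after neighbourhood correction, and 0.206 in part B with Spearman's coefficient. With replicate 2 as deposited in both parts, the means of ACACA, RAD21 and BNIP3 reversed to −0.043, −0.22 and −0.35. With it turned in both, those of RPL41, EREG, ZEB2 and PSMD5 reversed to 0.21, −0.17, −0.016 and 0.30. Leaving out 1 replicate gave means from −0.082 (without 3) to 0.010 (without 1) for TRAF1, −0.027 (without 2) to 0.59 (without 3) for BNIP3, −0.33 (without 1) to 0.086 (without 2) for PSMD5 and −0.59 (without 2) to 0.076 (without 3) for LOX. The other named means kept their sign under these settings, a dye term and centring, but of 80 clones the means of 27 moved by over 1.5 times with replicate 2 as deposited in both parts, of 30 with it turned in both, of 9 with a dye term, and of 12, 18 and 29 without replicates 1, 2 and 3. Signal over background was not used here.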

Other observations

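The tests in this part were chosen after seeing the result they measure, except the test of neighbouring genes and the turning of replicate 2 against the reading used. Genes with several clones give a further view of single genes. The GMNN clones, for the replication inhibitor geminin, had means of −0.19 and −0.18, which were −0.22 and −0.11 with replicate 2 turned. The 4 NR4A3 clones, for an orphan nuclear receptor of the immediate early class, had means from −0.29 to −0.04, and with replicate 2 turned 1 of them was at 0.27. ATF6, a sensor of the unfolded protein response, had clones at −0.63, 0.43 and −0.47. TP53BP1, a mediator of the response to DNA breaks, had clones at −0.38 (−0.70 with replicate 2 as deposited) and 0.22, and RAD1 had clones at −0.92 and 0.02, the latter −0.55 with replicate 2 turned. None of these passed the threshold.

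Replicates 1 and 3 shared part of their ratios, and replicate 2, with the dyes exchanged, shared little of it on average. A dye effect alone, or a difference between the RNA samples alone, makes a prediction if it has the same size on every array. The covariance of replicate 2 with the others is then as large as that between replicates 1 and 3, with either sign. On average it was −12.0% of it in part A and −14.7% in part B, where replicate 1 gave −46.0% (bootstrap interval −63.7 to −32.8) and replicate 3 gave 16.6% (4.78 to 28.7), opposite in sign. This argues against either as the whole cause if replicate 2 holds the samples on its label and carries the effect at the same size. A weaker effect on replicate 2 was not tested. After subtraction of the neighbouring spots, r between replicates 1 and 3 was 0.162 in part A and 0.166 in part B. Local background of the kind that this subtraction removes therefore fails as the whole cause, while background that it left was not measured. Replicate 2 was not noise of single spots alone. The 2 spots of a clone correlated on it with r = 0.306 in part B and 0.341 in part A after the same subtraction. In part B this was below replicates 1 (0.461) and 3 (0.379). Adjacent spots of different clones were not compared after the subtraction, so how much local background was left is not known. Another candidate is a mixture of dye effects and a difference between CloneK and Clone10 in the same proportions on every array. It would give replicate 2 the same sign with both others, or 0 for an equal mixture. The opposite signs in part B go against it, although the bootstrap treated clones as independent, so its intervals may be too narrow. In part A the signs were the same, with −6.91% (−15.8 to 2.35) for replicate 1 and −17.0% (−29.5 to −5.70) for replicate 3. A mixture that varies between arrays and an exchanged sample on replicate 2 stay open, untested.

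Different clones of a gene did not share ratios. A gene-level difference carried by replicates 1 and 3 would be seen in both if both report their named gene. After subtraction of the neighbouring spots, r between replicate 1 of one clone and replicate 3 of the other was 0.00666 (permutation p = 0.665), with an upper bound of 0.0383 against the 0.0811 that is 50% of the r of single clones. Clones with the same annotated sequence gave r = −0.0291 over 397 pairs (permutation p = 0.397). This goes against clones that cover other parts of a transcript as the cause only if names sit on the right spots. Names attached to the wrong spots could not be excluded or shown. The size of the difference between the 2 spots of a clone repeated across arrays (r from 0.162 to 0.265), and between clones with the same sequence it gave r = 0.0452 over 431 pairs (permutation p = 0.324) or 0.133 over 323 pairs with values on all arrays (permutation p = 0.022). Spot-specific effects of printing, misplaced names and the absence of a gene-level difference large enough to measure stay open.

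One hypothesis was that CloneK and Clone10 differ by large gains or losses of chromosome segments, which would give neighbouring genes a shared ratio. Over 6140 pairs of neighbouring genes, r between replicate 1 of a gene and replicate 3 of the next was −0.0142 (permutation p = 0.122, adjusted 0.183 over 3 pairs of arrays). Replicates 1 and 2 gave r = 0.0244 (permutation p = 0.00799, adjusted 0.024), and replicates 2 and 3 gave r = 0.0109 (permutation p = 0.231, adjusted 0.231). The test decides nothing about such segments, since it needs clones that report their named gene, and clones of one gene shared no ratio here. Another hypothesis was that p53 targets are higher in irradiated CloneK. Their median log2 ratio was −0.018 under the reading used, with a bootstrap interval from −0.15 to 0.05. The interval came from draws over the 17 genes, so it leaves out the spread between arrays. With replicate 2 turned in part B alone the median was 0.025. These values decide neither way with 17 genes that go in both directions.

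The number of clones at an unadjusted p under 0.05 was compared with the numbers under all 16 patterns of signs, with none or 1 array turned in each part. The reading used gave 1106, the highest of the others gave 1246, with replicate 2 turned in both parts, and 2 of the 16 patterns gave at least 1106. A set of 16 patterns is too small for a share under 0.05. Negative ratios outnumbered positive ones in the tails of all 6 arrays as deposited: in part B, 3.47% of spots on replicate 1 were at or below −1 and 1.87% at or above 1. At an unadjusted p under 0.05 there were 741 negative and 365 positive clones under the reading used, 669 and 285 with replicate 2 as deposited in both parts, and 748 and 498 with it turned in both.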
